A study of Mus musculus with 26 samples.

How the data were processed

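Per the labels' protocols, hearts were microdissected from mouse embryos of day 14, yolk sacs were genotyped, and single-end libraries of poly(A)-enriched RNA were made with a NEBNext kit and read for 75 bases on a NextSeq instrument. The authors deposited 1 file per library holding raw counts of reads per Ensembl gene, with no header and no summary rows. Per the submitters' processing notes, FastQC, Bowtie2, MACS2 and STAR 2.7.3a and the genome build mm10 were used for the series, with no role or order stated. The read counter, annotation version, strand setting and handling of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies, of overlapping genes and of antisense partners are therefore uncertain, and 6 of the 13 protein-coding genes of mitochondrial DNA held at most 5 counts in any library. All 6 files listed the same 37681 genes in the same order. Symbols were taken from a table of gene names for 32642 of them, and 28116 were matched by symbol to coordinates of GRCm38.p6, the same build as mm10. Coordinates are 1-based and are given for single genes only, since no genome or transcript annotation was used here.

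Samples were grouped by their titles and genotypes into 3 libraries labelled knockout and 3 controls, and 20 of the 26 samples of the series were not analysed here. The labels say that embryos were genotyped but not from how many litters they came, so p-values measure the spread between these samples. Total counts were 27876538, 27313124 and 31309760 in knockout replicates 1, 2 and 3 and 32078952, 28205643 and 29243056 in control replicates 1, 2 and 3. No 2 libraries were alike within sampling noise. The chi-square statistic per degree of freedom between libraries of 1 group was at least 20.2. The biological coefficient of variation was 18.0%.

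Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 2 groups, which left 15871, library sizes were scaled by TMM, and the groups were compared with the quasi-likelihood F test (glmQLFit, glmQLFTest). P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Fold changes are the libraries labelled knockout over the controls on the log2 scale, CPM values are TMM-scaled, and SE values were derived from the fold change and the F statistic. Principal components were taken from log2 CPM with a prior count of 2. Before the data were examined, 39 gene lists with 952 entries were fixed, covering heart and mitochondrial pathways, cell types of the heart and its neighbours, and quality. The 38 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. None of the 20 lists called with the preset correlation was called with an estimated one, and fry, which tests whether the genes of a list move on balance in 1 direction, called 10. For the interferon, histone and ventricular lists the estimated correlation (−0.0077, −0.11 and −0.024) lay below the preset 0.01. Correlated members therefore do not account for the loss of those calls. The named genes followed a rule also fixed then. They were the BET family, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and separated groups, leaving out predicted genes, and in each list up to 3 members past the threshold with the largest change, or else the 2 with the smallest p.

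The steps were tested on simulated data with the real means, library sizes and dispersions, for the comparison of the libraries labelled knockout with the controls. Over 15713 simulated genes, the fit recovered 13.4% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, and 5.92% of its calls were false. With sex as a covariate the recovered shares were 1.49%, 35.8% and 98.5%, and 11.3% of the calls were false, against 16.1% with the female libraries only. Most 1.5-fold changes were thus missed in the simulation, which held fewer changed genes than passed in the real data. It was a single data set with genes drawn independently and without an effect of sex. The false calls numbered 10 in the main fit, 12 with the covariate and 19 in the female libraries only. These shares are therefore only a rough guide to the real fits.

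Alternatives fixed before the data were examined were RLE and upper quartile scaling, no filter on low counts or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the robust quasi-likelihood fit, the replicate number as a block, leaving out each library in turn, leaving out haemoglobin, mitochondrial DNA or sex-linked genes, sex as a covariate, thinning to the smallest library, an adjusted p of 0.01, and glmTreat at a fold of 1.2. Fits on female libraries alone and without the 2 controls lowest in mitochondrial DNA counts were added after the data were seen.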

Results

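The deposited count tables covered 6 poly(A)-enriched RNA-seq libraries of mouse hearts microdissected at embryonic day 14, with 3 libraries in each of 2 groups. In the group labelled knockout, both copies of Brd4 carried loxP sites and the embryos carried Tnnt2-Cre, a recombinase driven by a cardiac troponin promoter that acts in cardiomyocytes. In the control group the embryos carried the same Cre and 1 floxed copy of Brd4, so the genotypes, if the Cre acted, set loss of both copies against loss of 1 copy in cardiomyocytes of whole hearts. The labels leave doubt about the Cre and the tissue. They list tamoxifen as a treatment in both groups, although Tnnt2-Cre is not an inducible form by its name, and they give the source as heart tissue and also as cardiomyocytes, while the protocol describes hearts, which are taken here as whole. Total counts lay between 27313124 and 32078952 per library, and between 20798 and 22015 genes had at least 1 count. The title of the series names BRD4, a bromodomain protein that binds acetylated chromatin, and mitochondrial homeostasis in cardiomyocytes. The comparison addressed which transcripts differ between embryonic hearts of these genotypes. The other 20 samples of the series, from adult cardiomyocytes, were not analysed here.

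Brd4 itself (ENSMUSG00000024002, chromosome 17, 32196272 to 32284743 on GRCm38.p6, protein-coding) was not lower in the libraries labelled knockout. It stood at 151 ± 16.8 CPM (SD, n = 3) in these and at 138 ± 26.5 CPM (SD, n = 3) in the controls, a log2 fold change of 0.13 ± 0.16 (SE; edgeR adjusted p = 0.614). Single libraries labelled knockout held 137, 147 and 170 CPM, and control libraries 164, 111 and 138 CPM. The counts cover whole genes, the labels do not name the deleted exons, and cells other than cardiomyocytes keep the gene, so these values do not check the deletion, and the group is called by its label throughout. Among the 4 tested members of the BET family, the bromodomain proteins to which BRD4 belongs, none passed the threshold over all genes or adjusted over the list alone. Brd3 differed by −0.27 (edgeR adjusted p = 0.195), Brd2 by −0.08 and the testis protein gene Brdt by −0.05 on the log2 scale. Brd2 changed sign to 0.0018 without control replicate 1, and Brdt to 0.0066 without knockout replicate 3 and to 0.18 without control replicate 2.

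The transcriptomes of the groups differed in 1469 of 15871 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 628 were higher and 841 lower in the libraries labelled knockout, and 210 and 348 of them differed at least 2-fold. All 1469 separated the 3 libraries labelled knockout from the 3 controls, as did 34.2% of all tested genes, where chance gives 10%. The first principal component held 48.4% of the variance and placed the libraries labelled knockout between −37.9 and −26.6 and the controls between 20.3 and 47.0. The count of 1469 rested on the replicates, since it was 381, 289 and 467 without knockout replicates 1, 2 and 3 and 728 without control replicate 2. By counts of Xist and Y-linked genes, the embryos of knockout replicates 1 and 3 were male and the other 4 female, and with sex as a term in the model, where 1 library labelled knockout shares its sex with the controls, 17 genes passed. Of the 82 named genes that passed, 34 also passed without each library in turn.

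**Figure D1:**
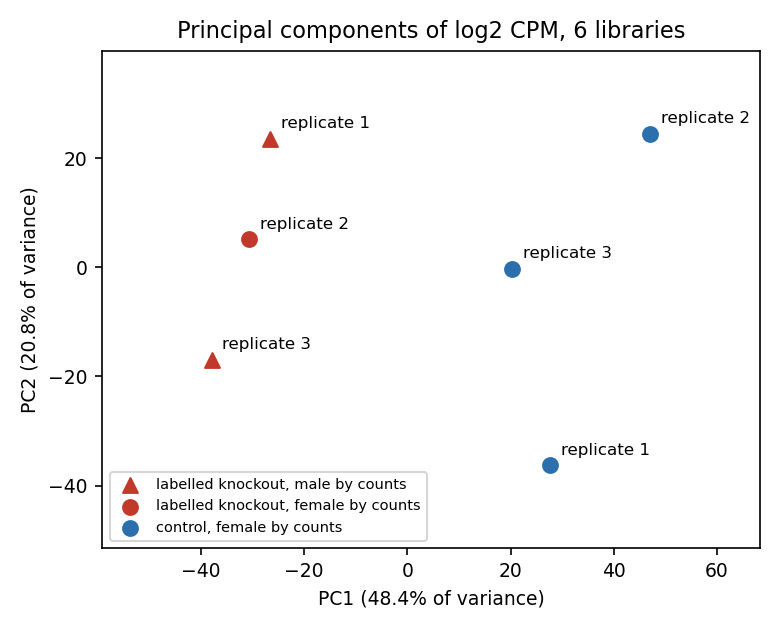
Scores of the 6 libraries on the first and second principal components of log2 CPM, in the units of the scores, with colour for the group and marker shape for the sex read from sex-linked counts. The libraries labelled knockout lie between −37.9 and −26.6 on the first component and the controls between 20.3 and 47.0.

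Among abundant genes, the 8 largest falls were those of Lrtm1, Ckmt2, Rec8, Dhrs7c, Cox8b, Doc2g, Ush1c and Crhr2. Errors are SD of the 3 libraries for CPM and SE for log2 fold changes, here and below. Lrtm1 (ENSMUSG00000045776, chromosome 14, 29018208 to 29033642) fell from 10.8 ± 2.56 to 0.430 ± 0.311 CPM, a log2 fold change of −4.60 ± 0.42 (SE, n = 3 and 3; edgeR adjusted p = 0.0013). Ckmt2 (ENSMUSG00000021622, chromosome 13, 91853386 to 91876923), the sarcomeric mitochondrial creatine kinase, fell from 11.3 ± 5.11 to 0.925 ± 0.229 CPM (log2 −3.60 ± 0.41). Cox8b (ENSMUSG00000025488, chromosome 7, 140898942 to 140900446), a muscle form of a cytochrome c oxidase subunit, fell from 44.0 ± 22.0 to 5.72 ± 0.865 CPM (log2 −2.94 ± 0.38). Doc2g (ENSMUSG00000024871, chromosome 19, 4003385 to 4007005) fell from 56.2 ± 14.1 to 7.31 ± 0.516 CPM (log2 −2.94 ± 0.19). Rec8, a meiotic cohesin subunit, Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, Ush1c and Crhr2, a receptor for urocortins, had log2 fold changes of −3.27, −3.19, −2.87 and −2.74. Ush1c lost its call without knockout replicate 1 or 2.

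By the same rule, with a mean of at least 5 CPM and without predicted genes, the 8 largest rises were those of Mybphl, Hspa1b, Angptl7, Fbln5, Acta1, Tmem56, Ildr2 and Sost. Mybphl (ENSMUSG00000068745, chromosome 3, 108364911 to 108380057), a myosin binding protein gene, rose from 3.91 ± 3.40 to 24.9 ± 2.09 CPM (log2 2.67 ± 0.50). Acta1 (ENSMUSG00000031972, chromosome 8, 123891758 to 123894775), the skeletal alpha-actin that the fetal and stressed heart also makes, rose from 95.9 ± 37.2 to 418 ± 145 CPM (log2 2.12 ± 0.32, edgeR adjusted p = 0.00783). Skeletal muscle genes were high in knockout replicate 3 alone, with Myh3 at 422 CPM there and at most 1.28 CPM elsewhere, and Acta1 stood at 278, 409 and 567 CPM in the libraries labelled knockout. Ildr2 (ENSMUSG00000040612, chromosome 1, 166254060 to 166316832) rose from 10.9 ± 0.821 to 47.2 ± 9.34 CPM (log2 2.12 ± 0.17). The heat shock gene Hspa1b (log2 2.44) has a near-identical neighbour, Hspa1a, with which it can share reads. Angptl7, the elastic fibre gene Fbln5, Tmem56 and Sost, an inhibitor of WNT signalling, had log2 fold changes of 2.40, 2.16, 2.12 and 2.06. Mybphl and Sost lost their calls without knockout replicate 1, and Fbln5 without knockout replicate 1 or 2 or control replicate 1 or 2. All 16 genes kept their direction without each library in turn, which the choice of genes with separated groups largely fixed beforehand.

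**Figure D2:**
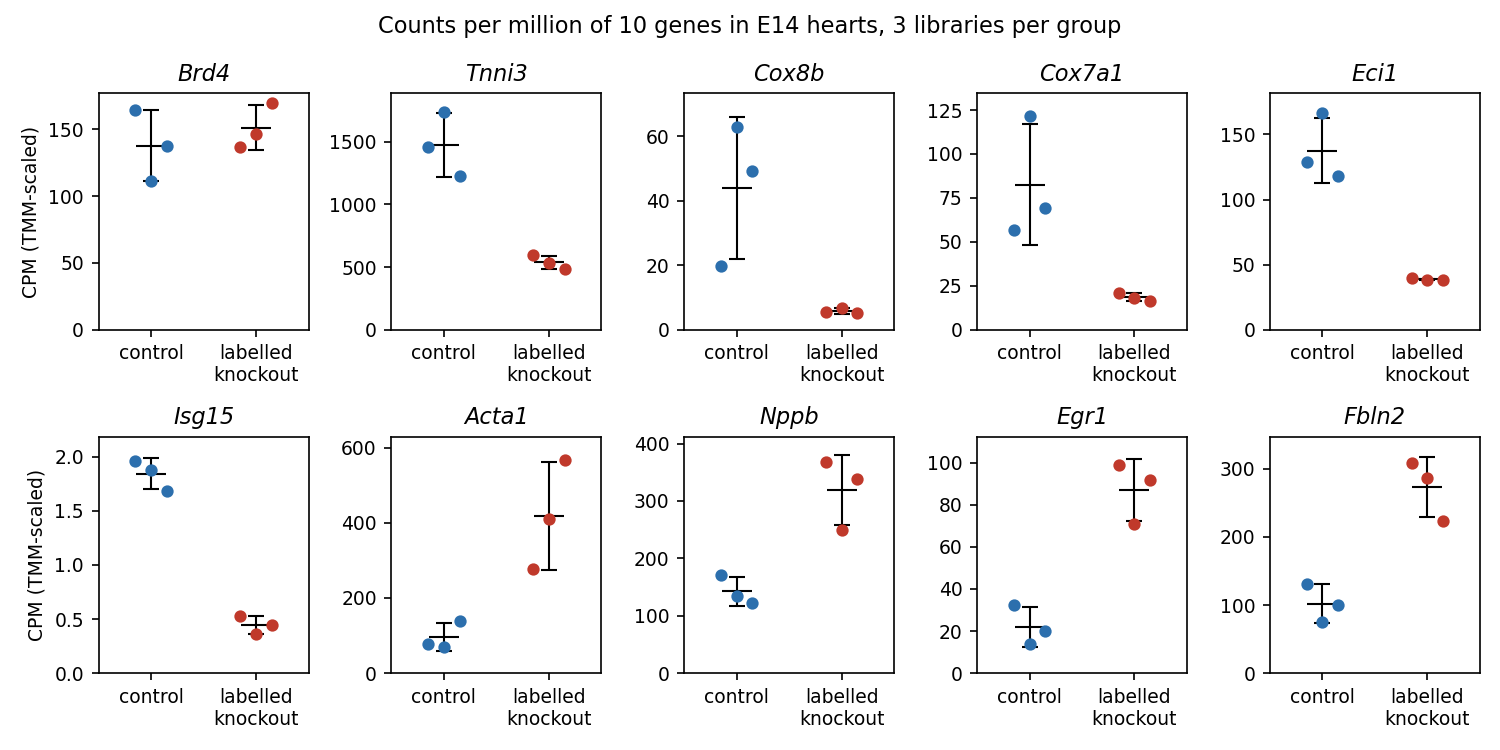
TMM-scaled CPM of 10 genes in single libraries (points), with the mean and SD of the 3 libraries of each group (black bar and whiskers) on linear axes that start at 0. Brd4 overlaps between the groups (138 CPM in controls and 151 CPM in the libraries labelled knockout), while Tnni3, Cox8b, Cox7a1, Eci1 and Isg15 lie lower and Acta1, Nppb, Egr1 and Fbln2 higher in all 3 libraries labelled knockout than in all 3 controls.

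Some nuclear genes of the electron transport chain, which encode most subunits of respiratory complexes, fell in the libraries labelled knockout. Of 80 tested members, 29 fell, none rose and 51 did not pass, and adjusted over the list alone 52 fell and none rose. Their median log2 fold change was −0.60, and 76 of 80 lay below 0. The muscle cytochrome c oxidase subunits Cox8b and Cox7a1 (from 82.5 ± 34.5 to 18.4 ± 2.40 CPM, log2 −2.16 ± 0.27) fell the most, and Cox6a1 fell from 492 ± 134 to 215 ± 30.1 CPM (log2 −1.19 ± 0.20), a call lost without knockout replicate 2. Per library, the list median against the control mean was −0.42, −0.65 and −0.67 in the libraries labelled knockout and −0.23, 0.32 and −0.05 in the controls. The camera test with a preset correlation of 0.01 called the list (adjusted p = 2.37e-18), but the call was lost with adjusted p = 0.476 with an estimated correlation, which was 0.66 between members, and fry gave 0.101. The median was −0.41 without control replicate 2.

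Of the 13 protein-coding genes of mitochondrial DNA 7 were tested, and 6 of these lay above 0 and mt-Nd6 below. Among the 7 none rose or fell, over all genes or adjusted over the list alone, and the median was 0.73. The largest was mt-Nd4, a complex I subunit, with 2103 ± 181 CPM against 707 ± 633 CPM (log2 1.57 ± 0.52, edgeR adjusted p = 0.0879), and mt-Nd2 differed by 1.10. The other 6 members held between 0 and 5 counts in every library and were not tested. Counts of mitochondrial DNA genes made up 3.78%, 3.97% and 3.44% of all counts in the libraries labelled knockout and 1.18%, 2.17% and 3.80% in the controls (exact permutation test, two-sided p = 0.3; 3 against 3 cannot give less than 0.1). Camera called the list (adjusted p = 0.0195), and the call was lost with adjusted p = 0.6 with an estimated correlation and without control replicate 1 (median 0.39, adjusted p = 0.21), and with DESeq2 (0.0956). Without control replicate 3 the median was 1.25 (adjusted p = 4.31e-09). Without the 2 controls lowest in mitochondrial DNA counts, a fit with 1 control, the median was 0.02. The control kept was picked by its share of 3.80%, so a small median follows from that choice.

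Some enzymes of fuel oxidation fell as well. Of 38 tested genes of fatty acid uptake and oxidation, 17 fell, 1 rose and 20 did not pass (adjusted over the list alone 23 fell and 2 rose), with a median of −0.57. Eci1 (ENSMUSG00000024132, chromosome 17, 24426683 to 24439316), an isomerase of beta-oxidation, fell from 138 ± 25.2 to 38.7 ± 0.555 CPM (log2 −1.83 ± 0.14, edgeR adjusted p = 0.000803), and the fatty acid transporter Cd36 from 183 ± 72.7 to 70.5 ± 5.64 CPM (log2 −1.38 ± 0.27). The lipid droplet gene Plin5 passed at a level near the detection limit, 0.551 CPM in controls and 0.0885 CPM in the libraries labelled knockout. The list passed in camera (adjusted p = 1.03e-11), with adjusted p = 0.194 with an estimated correlation, and fry gave 0.0155. Cd36 lost its call without each knockout replicate and control replicate 2, and Plin5 without knockout replicate 1 or 2. Of 27 genes of the tricarboxylic acid cycle and pyruvate oxidation, 8 fell, 1 rose and 18 did not pass (adjusted over the list alone 15 fell and 1 rose), with a median of −0.43. The pyruvate carrier subunit Mpc2 (log2 −1.36 ± 0.24), the succinyl-CoA ligase subunit Sucla2 (−0.97 ± 0.15) and the dihydrolipoamide dehydrogenase Dld (−0.81 ± 0.14) fell, but Mpc2 lost its call without each knockout replicate and Dld without knockout replicate 2 or 3. Camera called this list too (adjusted p = 8.33e-06), with adjusted p = 0.276 with an estimated correlation and 0.0155 in fry.

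Among regulators and upkeep genes of mitochondria some fell. Of 24 mitochondrial biogenesis regulators, 6 fell, none rose and 18 did not pass (adjusted over the list alone 9 fell and none rose), with a median of −0.17 (camera adjusted p = 0.00454; adjusted p = 0.276 with an estimated correlation). Perm1, a muscle regulator of oxidative genes, fell from 26.8 ± 10.1 to 8.80 ± 1.29 CPM (log2 −1.61 ± 0.27), and the nuclear receptor genes Ppara and Esrrb fell with log2 fold changes of −0.98 and −0.97. Perm1 and Esrrb lost their calls without knockout replicate 1, Esrrb also without knockout replicate 2, and Ppara without knockout replicate 1 or 2 or control replicate 2 or 3. Of 31 genes of mitochondrial dynamics and quality control, 4 fell, none rose and 27 did not pass (adjusted over the list alone 11 fell and none rose), with a median of −0.35 (camera adjusted p = 0.000518; adjusted p = 0.5 with an estimated correlation), and −0.22 without control replicate 2. The mitochondrial chaperones Hspd1 and Hspa9 (both −0.75) and the fusion gene Mfn1 (−0.70) were among the 4, and all 3 calls were lost without knockout replicate 1 or 2, those of the chaperones also without knockout replicate 3. In glycolysis, 6 of 24 tested genes fell, 2 rose and 16 did not pass (adjusted over the list alone 8 fell and 2 rose), with a median of −0.18 (camera adjusted p = 0.00213; adjusted p = 0.276 with an estimated correlation). The muscle enzymes Pgam2 (log2 −1.29 ± 0.16) and Eno3 (−1.15 ± 0.13) fell. Gapdh rose (0.93 ± 0.21), but its 71.7 and 37.7 CPM are low for this gene, which shares reads with pseudogenes, and its call was lost without each knockout replicate.

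**Figure D3:**
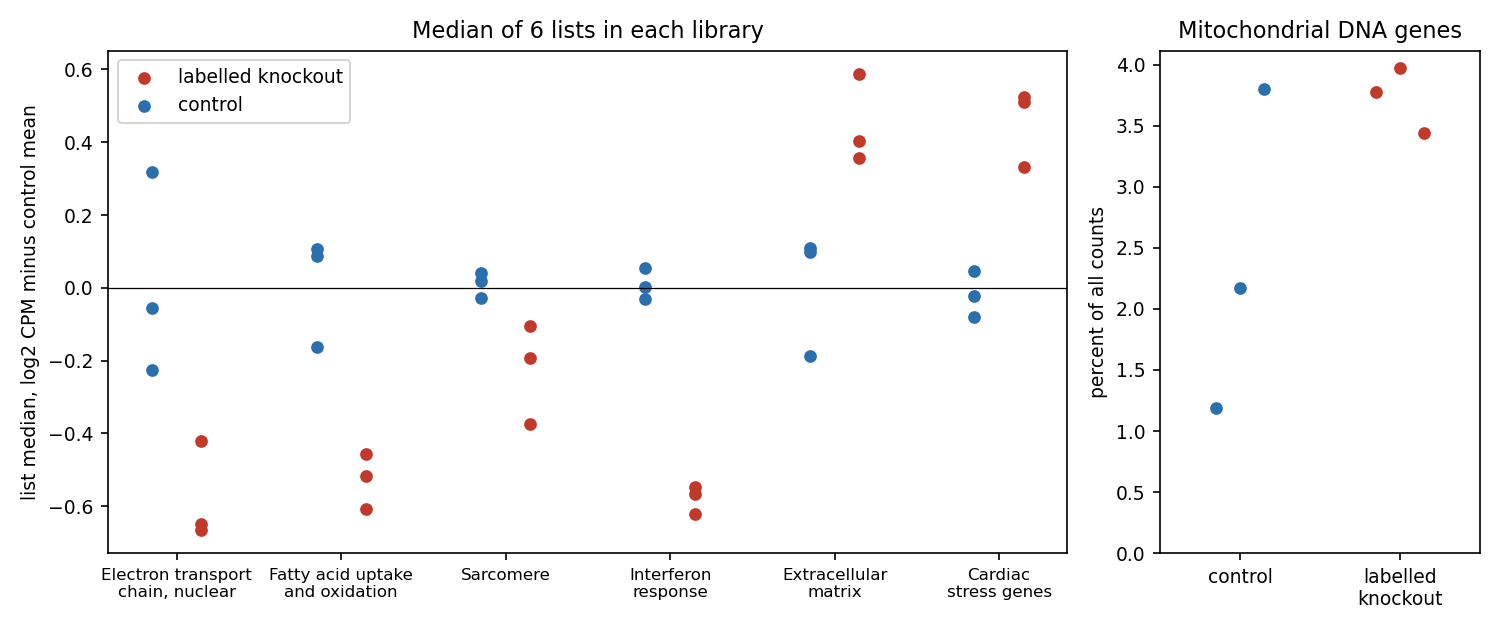
Left, the median of 6 fixed gene lists in each library, as log2 CPM minus the mean of the controls; right, the percentage of all counts on mitochondrial DNA genes in each library, on an axis from 0. The electron transport chain median lies between −0.67 and −0.42 in the libraries labelled knockout and between −0.23 and 0.32 in the controls, while the mitochondrial DNA share of control replicate 3, 3.80%, lies among those of the libraries labelled knockout.

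Contractile genes fell in part. Of 42 sarcomere genes, 10 fell, none rose and 32 did not pass (adjusted over the list alone 13 fell and 1 rose), with a median of −0.22. Tnni3 (ENSMUSG00000035458, chromosome 7, 4518305 to 4522718), the adult cardiac form of troponin I, fell from 1475 ± 253 to 538 ± 54.0 CPM (log2 −1.45 ± 0.16, edgeR adjusted p = 0.00265). The Z-disc gene Tcap fell by 1.46 and the thin-filament gene Lmod3 by 1.28 on the log2 scale. Camera called the list (adjusted p = 0.000166), with adjusted p = 0.194 with an estimated correlation. The skeletal muscle genes of knockout replicate 3 reached this list through Neb, at 51.1 CPM there and between 0.781 and 2.28 CPM in the other 5 libraries. Myh6, the alpha myosin heavy chain, stood at 11632 CPM in control replicate 1 and at no more than 3399 CPM elsewhere. Of 41 genes of calcium handling and ion channels, 11 fell, none rose and 30 did not pass (adjusted over the list alone 13 fell and 1 rose), with a median of −0.24. The potassium channel subunits Kcnip2 (log2 −3.70 ± 0.42) and Kcne1 (from 86.7 ± 10.2 to 17.0 ± 5.96 CPM, −2.35 ± 0.25) and the calsequestrin Casq1 (−1.36 ± 0.12) fell the most. Camera called this list (adjusted p = 8.42e-05), with adjusted p = 0.276 with an estimated correlation. Its median was −0.40 without control replicate 2 and −0.13 with sex as a covariate.

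Genes of cardiac stress rose in part. Of 19 tested members, 8 rose, none fell and 11 did not pass (adjusted over the list alone 10 rose and 4 fell), with a median of 0.51. Besides Acta1, Hspa1a (log2 2.48 ± 0.44) and Hspa1b, the natriuretic peptide gene Nppb rose from 143 ± 25.5 to 319 ± 61.2 CPM (log2 1.16 ± 0.18, edgeR adjusted p = 0.00964). Camera called the list (adjusted p = 8.42e-05), with adjusted p = 0.194 with an estimated correlation, and its median was 0.33 with sex as a covariate and 0.33 without a count filter. Among 24 immediate early genes, which respond within minutes to stimulation or tissue handling, 1 rose, none fell and 23 did not pass, with the same counts adjusted over the list alone. It was Egr1, from 22.2 ± 9.52 to 87.0 ± 14.6 CPM (log2 1.97 ± 0.28). Of 21 hypoxia response genes 2 rose, none fell and 19 did not pass, with the same counts adjusted over the list alone. They were P4ha2 (0.76) and P4ha1 (0.57), which hydroxylate collagen. The call of Hspa1a was lost without knockout replicate 1, that of P4ha2 without knockout replicate 2, and that of P4ha1 without each knockout replicate and control replicate 3.

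Some interferon response genes fell from low levels. Of 24 tested members, 7 fell, none rose and 17 did not pass (adjusted over the list alone 13 fell and none rose), with a median of −0.69 and 23 members below 0. Ifi44 fell from 4.66 ± 0.955 to 0.786 ± 0.461 CPM (log2 −2.55 ± 0.43), Isg15 from 1.84 ± 0.143 to 0.445 ± 0.0853 CPM (−2.04 ± 0.29, edgeR adjusted p = 0.00674), and Ifit1 differed by −2.20 at under 1 CPM, a call that any library left out ended. In camera the list passed (adjusted p = 2.47e-07), with adjusted p = 0.133 with an estimated correlation, and fry gave 0.00148.

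Some extracellular matrix genes rose. Of 45 tested members, 9 rose, 1 fell and 35 did not pass (adjusted over the list alone 21 rose and 1 fell), with a median of 0.44 and 38 members above 0. The elastic fibre genes Fbln5 and Mfap4 (from 47.4 ± 10.1 to 139 ± 36.4 CPM, log2 1.55 ± 0.22) and the matrix gene Fbln2 (from 102 ± 28.2 to 273 ± 44.3 CPM, 1.42 ± 0.21) rose the most. By camera the matrix list was higher (adjusted p = 4.73e-10), but with adjusted p = 0.276 with an estimated correlation and 0.0596 in fry it was not called. In the group of Notch, BMP, neuregulin and trabeculation genes, 6 of 39 rose, none fell and 33 did not pass (adjusted over the list alone 10 rose and none fell), with a median of 0.35. Nrg1, the neuregulin that signals to cardiomyocytes, rose by 1.26 ± 0.33, Bmp5 by 1.03 ± 0.24 and Dkk3 by 1.01 ± 0.26 on the log2 scale. Each of these 3 calls was lost in 5 of 6 fits with a library left out, and held only without control replicate 1 (Nrg1 and Dkk3) or control replicate 3 (Bmp5). Camera called this list (adjusted p = 0.00203), with adjusted p = 0.5 with an estimated correlation, and the median was 0.20 without control replicate 2.

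**Figure D4:**
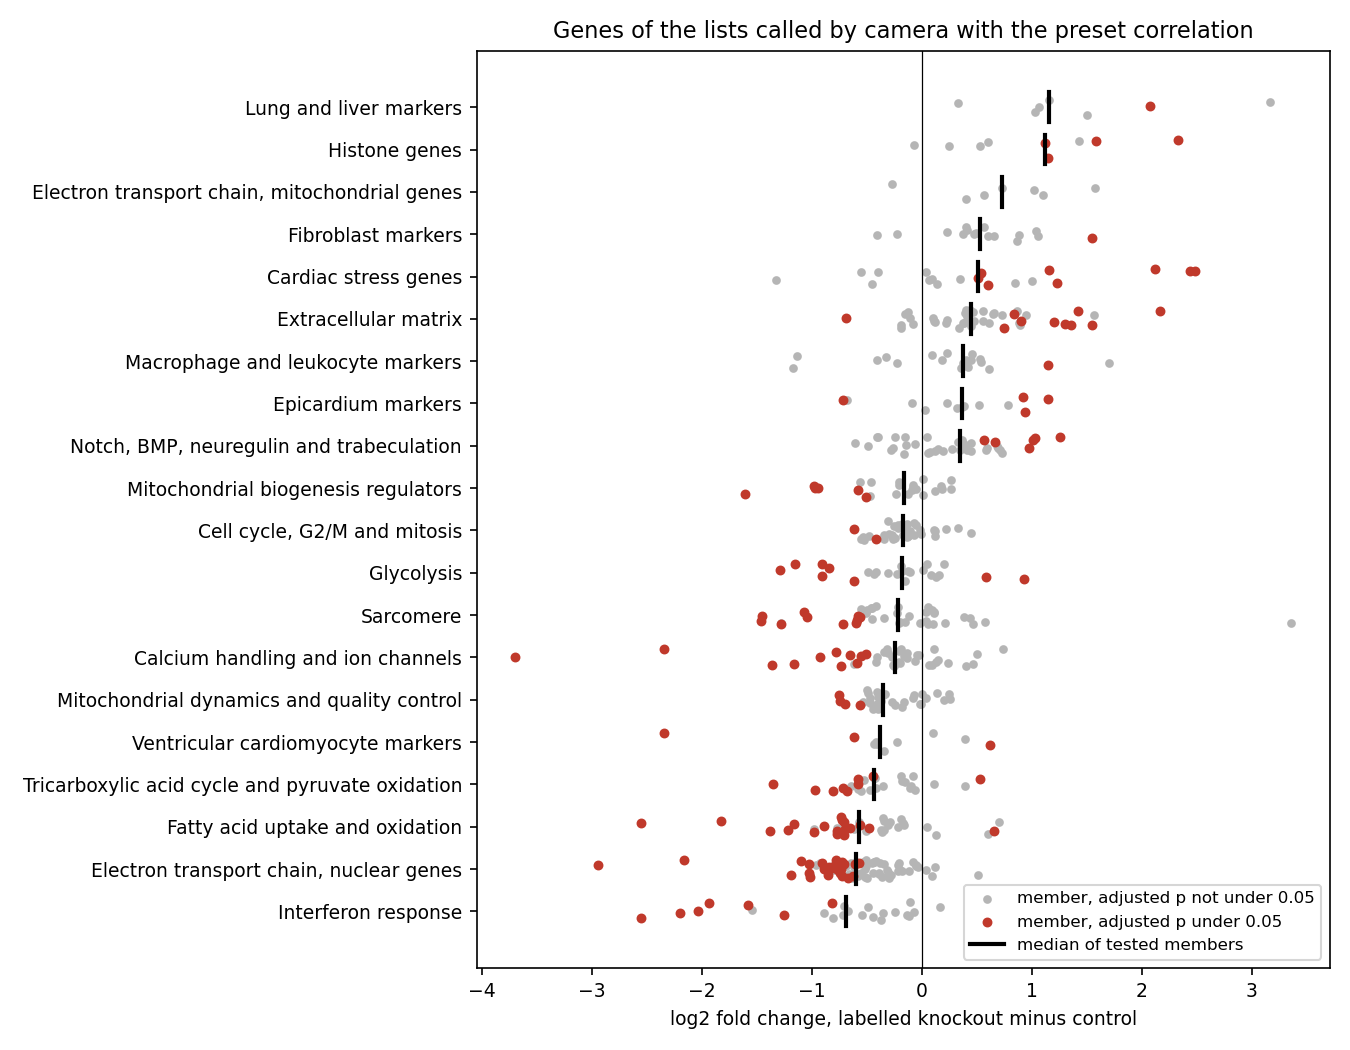
Log2 fold changes (labelled knockout minus control) of the tested members of the 20 lists that camera called with the preset correlation; points are genes, red where the edgeR adjusted p is under 0.05, with random vertical spread, and black bars are medians. The nuclear electron transport chain list has its median at −0.60 and the extracellular matrix list at 0.44; none of the 20 calls held with an estimated correlation.

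Markers of other cell types did not move alike. Of 16 fibroblast markers 1 rose, none fell and 15 did not pass, with the same counts adjusted over the list alone and a median of 0.53 (camera adjusted p = 0.000706; adjusted p = 0.352 with an estimated correlation). That gene was Mfap4. Of 13 epicardium markers 3 rose (Lrrn4 by 1.14, Msln by 0.94 and Bnc1 by 0.92 on the log2 scale), 1 fell and 9 did not pass, and adjusted over the list alone 5 rose and 2 fell. The epicardium median was 0.37 (camera adjusted p = 0.0174; adjusted p = 0.5 with an estimated correlation), and the call was lost without knockout replicate 1 (0.0851) or control replicate 3 (0.109) and with sex as a covariate (0.397), and the median was 0.24 without knockout replicate 3. Of 24 endothelial and endocardial markers 5 rose, 4 fell and 15 did not pass (adjusted over the list alone 5 rose and 6 fell), with a median of 0.02. Eng (0.88 ± 0.15) and Vwf (0.92 ± 0.23) rose while the tight junction gene Cldn5 (−1.24 ± 0.29) fell. Among 13 smooth muscle and pericyte markers 1 rose (Itga8, 0.59), 1 fell (Cnn1, from 158 ± 33.9 to 70.2 ± 1.03 CPM) and 11 did not pass, and adjusted over the list alone 3 rose and 2 fell. None of 12 valve mesenchyme markers passed, over all genes or adjusted over the list alone, although camera called that list without knockout replicate 3 (median 0.46, adjusted p = 0.00759) and with sex as a covariate (0.0173). In the macrophage and leukocyte list 1 of 19 rose (Fcgr3, 1.14), none fell and 18 did not pass, and adjusted over the list alone 4 rose and 1 fell. Its median was 0.37 (camera adjusted p = 0.0331; adjusted p = 0.545 with an estimated correlation), and the call was lost without knockout replicate 1 (0.274), control replicate 1 (0.345) or control replicate 2 (0.0776) and with sex as a covariate (0.308). None of 19 erythroid markers passed, over all genes or adjusted over the list alone; Hbb-y, an embryonic globin, differed by −1.43 ± 0.57 and Gata1 by 0.99 ± 0.41. Of 8 neural and Schwann markers 1 rose (Sox10, 0.104 to 1.20 CPM), 1 fell (Dbh, 0.813 to 0.204 CPM) and 6 did not pass, as adjusted over the list alone. With a library left out, Vwf and Fcgr3 passed only without control replicate 3, Cldn5, Itga8 and Dbh only without control replicate 1, and Sox10 only without knockout replicate 1. Msln lost its call without each knockout replicate and control replicate 2, Bnc1 without knockout replicate 1 or 3, and Eng without knockout replicate 1 or 2.

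Markers of skeletal muscle and of lung and liver had their highest medians in knockout replicate 3, at 4.15 and 2.13 on the log2 scale against the control mean. Of 8 skeletal muscle markers none rose, 1 fell and 7 did not pass (adjusted over the list alone 2 rose and 1 fell). The gene that fell was Ckm, a creatine kinase that heart also makes, from 230 ± 144 to 49.2 ± 16.3 CPM (log2 −2.22 ± 0.49), a call that held only without control replicate 1 when libraries were left out in turn. Without knockout replicate 2 camera called this list (adjusted p = 0.0477). Of 7 lung and liver markers 1 rose, none fell and 6 did not pass (adjusted over the list alone 3 rose and none fell), with a median of 1.16. The riser was the liver gene Ahsg, from 1.65 ± 0.820 to 6.97 ± 0.128 CPM, and it was high in all 3 libraries labelled knockout (7.10, 6.85 and 6.96 CPM). The liver genes Alb, Afp, Fgb and Serpina1a were below the count filter and not tested. Camera called the list (adjusted p = 0.00599), with adjusted p = 0.476 with an estimated correlation, and the call was lost without knockout replicate 3 (median 0.26, adjusted p = 0.187) or with sex as a covariate (median 0.14). The median was 1.87 without knockout replicate 2 and 1.77 without a count filter.

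Cardiomyocyte subtypes and cardiac regulators showed changes in single genes. Of 10 ventricular markers 2 fell (Kcne1 and the transcription factor Irx4, −0.62), 1 rose (Lrrc10, 0.62) and 7 did not pass, and adjusted over the list alone 6 fell and 2 rose. The median was −0.38 (camera adjusted p = 0.0481; adjusted p = 0.276 with an estimated correlation), and the call was lost without knockout replicate 1 (0.116), control replicate 1 (0.083) or control replicate 3 (0.0724), with the stricter count filter (0.0603), with limma-voom (0.1) and with sex as a covariate (0.189). Of 12 atrial markers 1 rose (Bmp10, 0.98), 1 fell (Nr2f1, −1.05) and 10 did not pass, and adjusted over the list alone 3 rose and 2 fell. Of 12 trabecular markers 3 rose, 2 fell and 7 did not pass (adjusted over the list alone 4 rose and 2 fell); Nppb and Bmp10 rose and Cited1 fell (−0.90), and camera called the list without control replicate 1 (adjusted p = 0.0357) and without X- and Y-linked genes (0.0311). Of 10 compact myocardium markers 1 fell (Mycn, −0.56), none rose and 9 did not pass, as adjusted over the list alone. Among 35 cardiac transcription factors 1 rose, 3 fell and 31 did not pass (adjusted over the list alone 2 rose and 4 fell). Isl1, a factor of early progenitors and the sinoatrial node, stood at 1.27 ± 0.571 CPM against 0.147 ± 0.0132 CPM in controls (log2 3.06 ± 0.47), and Nr2f1, Irx4 and Mycn fell. Of 16 regulators of P-TEFb, the kinase that releases paused RNA polymerase, 1 fell (Larp7, −0.66), none rose and 15 did not pass, and adjusted over the list alone none passed. With libraries left out in turn, Larp7 and Mycn passed only without control replicate 3. Irx4, Lrrc10, Nr2f1 and Cited1 lost their calls without each knockout replicate, Lrrc10 and Cited1 also without control replicate 2 and Nr2f1 without control replicate 3, and Bmp10 without knockout replicate 2 or 3 or control replicate 2 or 3.

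In the lists of growth and stress few genes passed outside the histones. Of 36 genes of G1/S and replication 1 fell (Cdc6, −0.45), none rose and 35 did not pass, and adjusted over the list alone none passed; camera called the list without knockout replicate 1 (adjusted p = 0.0386), with sex as a covariate (0.036), without a count filter (0.0246) and with limma-voom (0.025). Of 37 genes of G2/M and mitosis 2 fell (Cdc25c by 0.62 and Bub1b by 0.41 on the log2 scale), none rose and 35 did not pass, and adjusted over the list alone 1 fell. The G2/M median was −0.17 (camera adjusted p = 0.0253; adjusted p = 0.654 with an estimated correlation), and the call was lost without knockout replicate 2 (0.0521), knockout replicate 3 (0.0553), control replicate 2 (0.152) or control replicate 3 (0.0854). None of 30 genes of p53 targets and apoptosis passed, over all genes or adjusted over the list alone; Aen differed by 0.50 and Cdkn1a by 0.56. Of 33 genes of the integrated stress response 1 rose (Pycr1, 0.71), 3 fell (among them Aldh1l2, −0.79, and Phgdh, −0.73) and 29 did not pass, and adjusted over the list alone 1 rose and 7 fell. Camera called that list without knockout replicate 1 (adjusted p = 0.0354) or control replicate 3 (0.0481), with sex as a covariate (0.0358) and without a count filter (0.0356). None of 23 cholesterol synthesis genes passed, over all genes or adjusted over the list alone, with Pmvk at −0.51 and Sc5d at 0.44, and camera called them lower with sex as a covariate (median −0.31). Of 9 histone genes 4 rose, none fell and 5 did not pass (adjusted over the list alone 5 rose and none fell), with a median of 1.12 (camera adjusted p = 0.000156; adjusted p = 0.194 with an estimated correlation), and 0.58 without a count filter. Hist1h2bc rose by 1.58 ± 0.24, Hist1h1c by 1.14 ± 0.25 and Hist2h3c2 by 2.33 ± 0.49 on the log2 scale; most histone transcripts lack a poly(A) tail and have near-identical copies, so these counts are uncertain. With libraries left out in turn, Bub1b passed in no fit, Cdc6 and Phgdh only without control replicate 3, Pycr1 and Hist1h1c only without control replicate 1, and Aldh1l2 only without knockout replicate 2. Cdc25c lost its call without each knockout replicate and control replicate 2, and Hist2h3c2 without knockout replicate 1 or 2. The median of the p53 list (−0.07) and of the immediate early list (−0.12) had the opposite sign to their camera direction, and the mean of the P-TEFb list (−0.0055) and of the endothelial list (−0.0079) the opposite sign to their medians.

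Sex-linked genes split the libraries by sex, which was unevenly spread over the groups. Xist, which is transcribed from the inactive X chromosome, had 5, 20912 and 16 counts in knockout replicates 1, 2 and 3 and 29534, 12126 and 24023 in control replicates 1, 2 and 3. The Y-linked Ddx3y had 2050, 0 and 2376 counts in the former and 4, 1 and 0 in the latter. Of the 1469 changed genes 1375 were autosomal and 48 lay on the X chromosome. The Y chromosome held 0 of them, but the Y-linked list members Ddx3y, Uty, Kdm5d and Eif2s3y were below the count filter. The rest had no chromosome in the table used or lay on mitochondrial DNA, which were not counted apart. The only list member tested was Xist (log2 −1.54, edgeR adjusted p = 0.617), and it neither rose nor fell, over all genes or adjusted over the list alone. Without knockout replicate 2 it passed with a log2 fold change of −11.02.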

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

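The fits on female libraries only and without the 2 controls of lowest mitochondrial share were chosen after the data were seen. All 1469 genes changed between the groups kept their direction wherever they were tested in the 21 other fits. Their complete separation of the libraries largely fixed this beforehand, so it is no separate support. The number past the threshold moved widely. DESeq2 called 2599 genes (1119 higher and 1480 lower), and without a filter on low counts 1300 genes were lower. Leaving out each library in turn gave 289 to 1410 genes, 108 to 560 higher and 181 to 890 lower. The replicate block gave 822 genes, 315 higher and 507 lower, of which 790 were among the 1469. Libraries that share a number correlated at −0.18, −0.13 and 0.04 in their deviations from group means, and no pair of equal number was the best match of both libraries, so the numbers were not taken as pairs. Sex as a covariate left 17 genes (6 higher and 11 lower), 16 of them among the 1469, and the female libraries only 18 (6 higher and 12 lower). Both rest on the single female library labelled knockout, so the spread of that group is not measured within that sex, and in the simulation 11.3% and 16.1% of their calls were false. With that covariate the fold changes of the 1469 had a median ratio of 1.00 to the reported ones, and their median SE rose from 0.168 to 0.263. These genes were chosen in a fit that held the female library labelled knockout, so a ratio near 1.00 was in part built in. Why the calls were lost was not tested. Without the 2 controls lowest in mitochondrial DNA counts, 247 genes passed (53 higher and 194 lower), with a median ratio of 0.868. That fit has 1 control library and takes its spread from the other group alone, so its count says little, and the cause was not tested. By construction fewer genes passed an adjusted p of 0.01 (233, of which 87 higher and 146 lower) or glmTreat at a fold of 1.2 (583, of which 232 higher and 351 lower).

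Between 18 and 23 lists were called by camera in the other fits, against 20, but 0 with an estimated correlation and 10 with fry. Fry called the sarcomere, calcium handling, tricarboxylic acid cycle, fatty acid, mitochondrial biogenesis, glycolysis, cardiac stress, interferon, ventricular and histone lists (adjusted p between 2.63e-06 and 0.0394). The nuclear electron transport chain median of −0.60 stayed between −0.70 and −0.41 and was called in all fits with the preset correlation, but not with an estimated correlation (adjusted p = 0.476) or fry (adjusted p = 0.101). The Brd4 log2 fold change stayed between 0.0056 and 0.27 and passed in no fit. Reversals were limited to results that had not passed, and their cause was not tested. Brd2 lay between −0.16 and 0.0018 with each library left out and at 0.053 without the 2 controls of lowest mitochondrial share. Brdt lay between −0.24 and 0.18 with each library left out, at 0.12 with sex as a covariate and at 0.13 in the female libraries only. Xist lay at 0.047 with sex as a covariate and at 0.054 in the female libraries only, where the design removes the male libraries. The erythroid markers were called lower with sex as a covariate (median −0.46) and in the female libraries only (median −0.46). Of the 82 named genes that had passed, 34 passed without each library in turn. None reversed, which their separation of the groups largely fixed beforehand. Leaving out knockout replicate 1, 2 or 3 ended 43, 42 and 34 calls. In the simulation 13.4% of 1.5-fold and 89.6% of 2-fold changes were recovered.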

Other observations

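Gene families other than the fixed lists, chosen after their values were seen, also held changed genes, without a set test. Some members, such as Ckm, are also in the fixed lists and were reported above. Of 11 creatine and adenylate kinases 5 fell and 1 rose, with Ak1 falling from 334 to 98.8 CPM (log2 −1.76 ± 0.16) and Ckb from 147 to 79.6 CPM (−0.89 ± 0.15) beside Ckm and Ckmt2, while the scarce Ak5 rose. Of 76 mitochondrial ribosome genes 7 fell and none rose, among them Mrpl34 (−0.99 ± 0.24) and Mrpl12 (−0.97 ± 0.17), and 64 lay below 0. Adjusted over that family alone 18 fell and none rose, and its median of −0.25 was near that of the proteasome, Sm and LSm genes (−0.24), of which 1 of 58 fell. Of 28 assembly factors of respiratory complexes 5 fell and none rose, the largest being Ndufaf5 (−0.94 ± 0.21). Of 41 mitochondrial carriers of the Slc25 family 6 fell and 1 rose, with a median of −0.07. Slc25a19, which carries thiamine pyrophosphate, fell from 46.1 to 19.9 CPM (−1.21 ± 0.12).

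Enzymes that modify collagen, again chosen after their values were seen, rose in part. Of 22 tested, 11 rose, none fell and 21 lay above 0, with a median of 0.61 that was also 0.61 with RLE or upper quartile scaling. P4ha1 and P4ha2 of the hypoxia list are among the 11. Lox, which cross-links collagen and elastin, rose from 33.7 to 83.4 CPM (1.30 ± 0.16), the prolyl hydroxylase P3h2 from 31.4 to 73.0 CPM (1.22 ± 0.19) and the lysyl hydroxylase Plod2 from 85.1 to 168 CPM (0.98 ± 0.12). No set test was run on them, and the fibroblast markers (median 0.53) and the matrix list (0.44) were higher too. Beside the interferon genes, 3 of 4 tested immunoproteasome genes fell, namely Psmb10 (−1.54), Psme2 (−1.29) and Psme1 (−1.27). Psmb10 is also the 1 gene that fell among the proteasome, Sm and LSm genes above.

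The tests of marker divergence, globin, sex, label exchange and exons below were chosen after the results were seen. For the number of changed genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; the real split gave 1469 genes, and 1 of the 10 splits gave as many, the highest of the others giving 1. For the lists the real split gave 20 and the highest of the others 15, again with 1 of 10 as large. The other splits called between 7 and 15 lists. Each of them holds the 2 groups in unequal numbers on its sides, so part of the group difference remains in it. They do not show how many lists the preset correlation would call without that difference.

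For the lower nuclear electron transport chain genes, a smaller share of cardiomyocyte RNA as the whole cause stays open. Fibroblast and epicardium medians parted from endothelial and smooth muscle medians by 0.43 ± 0.08 (SD, n = 3) in the libraries labelled knockout, against 0.02 ± 0.15 in controls. A mere loss of cardiomyocytes would raise all these markers alike, provided that cardiomyocytes make none of them, which was not tested. The lists were also paired in this way after their medians were seen, so a gap was known beforehand and does not decide the question. The sarcomere median exceeded the electron transport chain median by 0.36 ± 0.27 in the libraries labelled knockout, but in knockout replicate 1 only by 0.05, within the range of the controls. The cardiac troponin gene Tnnt2 stood at 6416 ± 344 CPM in the libraries labelled knockout and at 8780 ± 361 CPM in controls, with no overlap. A smaller share may thus contribute. For a loss of short transcripts, proteasome and spliceosome genes had a median of −0.22 ± 0.15, and the electron transport chain median lay below theirs by 0.36 ± 0.02 in the libraries labelled knockout and above it by 0.03 ± 0.11 in controls, which an equal loss in both sets would not give, but the explanation stays open because transcript lengths were not available and the bound set beforehand was met by only 0.02 in 2 libraries, less than the control SD of 0.12. For younger embryos in the group labelled knockout, the embryonic globin Hbb-y made up 28.2 ± 9.56% of beta-globin counts there and 55.6 ± 21.6% in controls (exact permutation test, two-sided p = 0.1, the smallest possible). That is the opposite of what youth would give, but the ranges nearly touched, at 17.4% to 35.5% and 37.1% to 79.3%. The share reflects the blood in each sample and not the heart itself. Carryover of other tissue was not told apart from age. The liver gene Ahsg was higher in the libraries labelled knockout, but Alb, Afp, Fgb and Serpina1a were below the count filter. Ahsg alone therefore does not show carryover of liver, and the age of the hearts stays open. Loss of Brd4 in cardiomyocytes, the difference the labels name, remains among the open explanations.

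The groups differ in sex, with 2 of 3 libraries labelled knockout male and all controls female. Genes called between the male libraries labelled knockout and 2 controls were followed in the female library labelled knockout against the held-out control. Of 286, 260 and 79 such autosomal genes, 95.8%, 98.5% and 97.5% went the same way, against 69.0%, 71.0% and 77.1% of all autosomal genes, where sex alone would give about as many each way. With control replicate 1, 2 and 3 held out, their median log2 change was 1.43, 1.36 and 1.88 in the fits with the male libraries. In the female pair it was 0.96, 1.34 and 1.41 in the same direction. Sex is therefore argued against as the cause of most of these calls, although all 3 shares rest on the same female library.

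Brd4 counts were not lower in the libraries labelled knockout. On the first principal component the groups stood 46.9 apart with no overlap. This bears on an exchange of single libraries between the groups only if that component follows the genotype. No value here ties it to the genotype, so such an exchange stays open. An exchange of all labels would leave the gap unchanged and was not tested. Reads of exons outside the deleted part may keep the count of the whole gene near that of controls, here at a log2 fold change of 0.13, and without counts per exon this cannot be told apart from an incomplete deletion or from Brd4 of other cell types.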
